A study of Mus musculus with 12 samples.

How the data were processed

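Messenger RNA of C2C12 myoblasts was measured in 12 libraries, 3 in each of 4 groups: growth medium with PBS, growth medium with acetoacetate, differentiation medium with PBS and differentiation medium with acetoacetate, each treatment lasting 12 h per the labels. Cells were lysed with TRIZOL in the dish and libraries were made by a standard Illumina protocol, per the labels' protocols. Reads were aligned with BWA 0.5.9-r16 to mm9, per the submitters' processing notes. The rule for assigning reads to genes, the treatment of reads with several matches, the strand of the library and the gene annotation are not given in the sources used here.

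The deposited table held raw read counts and RPKM values of 23446 genes in the 12 libraries, with each gene's length, per the file headers. RPKM recomputed from the deposited counts, the lengths and a single divisor per library matched the deposited RPKM within 0.0005%, and the counts summed to 63.2% to 64.9% of that divisor. Counts were used in each test. RPKM served only to check the units, to give an alternative library size and to set the lowest level for naming genes. Every column was matched to a sample of the labels (0 unmatched). Gene names, GC content and exon overlaps came from GENCODE M21 on GRCm38. The overlaps were computed from its exon coordinates, whereas the reads were aligned to mm9. By name, 23070 genes (98.4%) were matched, and 12143 of the tested genes (99.3%) had a GC content.

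Reads per library are given in the report; 14530 to 14798 genes had at least 1 read, and the 10 most abundant genes took 5.2% to 6.2% of the counts. Genes were kept by edgeR's filterByExpr by group, which left 12230 genes and 99.9% of the counts in each library. Libraries were scaled by TMM, and 1 model with 4 group means was fitted to the 12 libraries with edgeR's quasi-likelihood method (glmQLFit and glmQLFTest, two-sided), so that the 4 groups share 1 estimate of the spread (8 residual degrees of freedom, median prior degrees of freedom 24.8, common biological coefficient of variation 4.08%). Between 2 libraries of a group, the chi-square per degree of freedom of the counts was 1.46 to 2.94, where 1 is counting noise alone. P-values were adjusted by Benjamini and Hochberg over the tested genes of a comparison, and the threshold was a 5% false discovery rate (FDR). The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F; the median SE in the GM comparison was 0.081. CPM values were scaled with TMM.

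The comparisons were AA against PBS in GM, AA against PBS in DM, DM against GM in PBS, and the difference of the 2 AA effects (DM minus GM). The first 2 share no library, and their overlap was tested with Fisher's exact test (one-sided) on genes past the threshold in the same direction. The comparison of media uses the PBS libraries of both, so it shares a control group with each AA comparison, and no correlation or overlap was computed between it and them.

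A total of 27 gene lists were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. They cover G1/S and DNA replication, G2/M and mitosis, cell cycle exit, ERK-responsive and immediate early genes, myogenic regulators, sarcomere and contractile genes, myoblast fusion, Notch and Id, IGF and atrophy, ketone body metabolism and transport, sterol synthesis, fatty acid oxidation and PPAR targets, TCA cycle and respiratory chain, glycolysis, NRF2 and oxidative stress, ER stress and integrated stress response, p53 targets, inflammation and NF-kB, interferon response, extracellular matrix and TGF-beta, ribosome biogenesis and control genes, and markers of 5 other cell types (adipocyte, osteoblast and chondrocyte, epithelial, immune and endothelial). Lists with at least 5 tested members, 22 in all, were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A call with the preset correlation counts as past the test, and the value with the estimated correlation stands beside it.

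The text names, in each comparison, (a) the 6 higher and the 6 lower genes with the largest fold change past 5% FDR whose 3 libraries of one group all lie on the called side of the other 3 and whose higher group has a mean of at least 5 (RPKM), or for the difference of effects the 4 highest and 4 lowest, without the range condition; (b) up to 4 members of each list past 5% FDR with the smallest p, of which some are left out, mostly members whose calls were lost under an alternative, so the examples shown are more stable than the lists as a whole; and (c) Ccnd1, Mki67, Myod1, Myog, Pax7, Cdkn1a, Myh3, Ckm and Oxct1 in each comparison. Predicted genes and genes without a symbol were passed over in (a). Gapdh, Ppia, Rpl10 and Trim63, and the genes named in the closing section outside these rules, were chosen after their values were seen. For a gene with 0 reads in a group the fold change is a bound against a floor of 3 counts over the group, and for genes with few reads the ratio has a 95% interval from the exact binomial test on summed counts.

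The pipeline was tested on simulated data: counts were drawn for all 12 libraries from the mean levels of GM-PBS, with 200 genes changed in GM-AA, and the model of 4 groups was fitted. Among 12007 genes tested, 58.2% of the changed genes were recovered at 1.25-fold (39 of 67), 79.1% at 1.5-fold (53 of 67) and 92.4% at 2-fold (61 of 66), and 6 of 159 calls were false. Genes at low levels were not among those changed, and far more than 200 genes were called in GM (2534). These rates may therefore not carry over to the data. Alternatives written before the data were examined were DESeq2's size factors (RLE), no filter on low counts, a filter of at least 50 reads in at least 3 libraries, DESeq2's Wald test, a fit of only the groups compared, the replicate number as a block, edgeR's robust option, an added threshold of 1.5-fold, unadjusted p-values for the overlap, and leaving out each library. Alternatives written for normalized values (a pseudocount, quantile normalization, other scaling of normalized values, limma without a trend) were not run, since counts were tested. Chosen after the data were seen were the library size taken from the RPKM divisor, the list and overlap results under several of these settings, and an offset removing each library's trend with GC content and gene length (natural splines with 4 degrees of freedom). Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15.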

Results

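RNA was sequenced from C2C12 cells, an established line of mouse skeletal muscle myoblasts that divides in growth medium (GM) and stops dividing and fuses into myotubes in differentiation medium (DM). In each medium the cells received acetoacetate (AA), a ketone body that tissues take up and oxidise, or PBS as the control, for 12 h. The labels give neither the salt of AA nor whether PBS was matched for it, so an effect of AA here includes that of any counter-ion. The 4 groups, GM-PBS, GM-AA, DM-PBS and DM-AA, held 3 libraries each, and the stated purpose was to find the genes that respond to AA during proliferation and during differentiation. Reads assigned to genes summed to 8292006 to 8965129 per library in GM-PBS, 8484417 to 8801619 in GM-AA, 7959519 to 9893564 in DM-PBS and 8027518 to 8245402 in DM-AA. Of 23446 genes, 12230 had enough reads to be tested. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Unless stated otherwise, values are log2 fold changes ± SE from edgeR's quasi-likelihood test with n = 3 libraries per group, and "past the test" means a Benjamini-Hochberg adjusted p under 0.05 over all tested genes.

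The 4 groups separated fully in a principal component analysis of log2 CPM (reads scaled by library size). The first component, 65.0% of the variance, parted the media, and the second, 13.3%, parted AA from PBS in both media. Libraries of a group correlated at 0.993 to 0.995 across genes (Pearson, log2 CPM), against 0.989 to 0.990 between GM-AA and GM-PBS, 0.985 to 0.989 between DM-AA and DM-PBS, and 0.964 to 0.966 between DM-PBS and GM-PBS. Genes are not independent replicates, so no test was attached to these correlations.

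**Figure D1:**
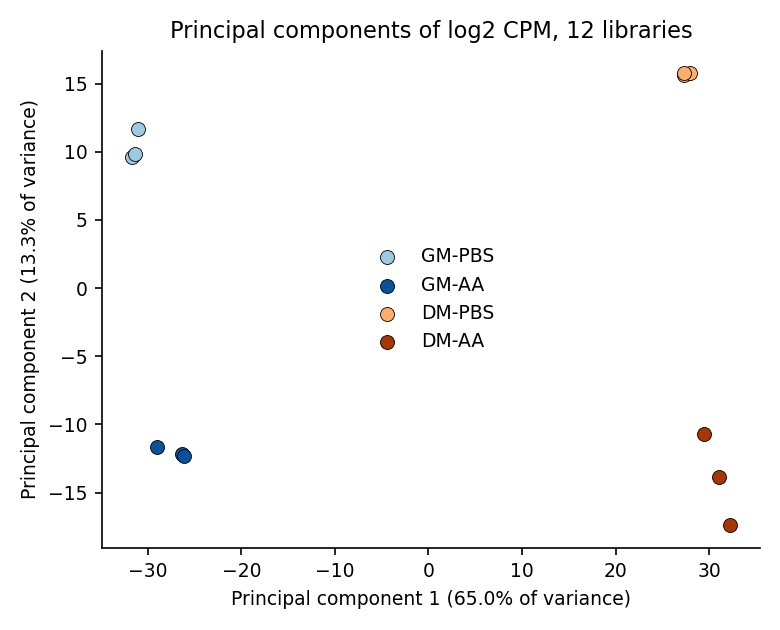
Principal components 1 (65.0% of the variance) and 2 (13.3%) of log2 CPM over the 12230 tested genes, 1 point per library, coloured by group. Component 1 separates the 6 GM libraries from the 6 DM libraries and component 2 the 6 AA libraries from the 6 PBS libraries.

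Each library's deviation from the gene means also followed the GC content of the transcripts, and this trend moved with AA. Spearman's rho across 12143 genes was 0.00566 to 0.211 in the GM-PBS libraries and -0.177 to -0.115 in the GM-AA libraries, and 0.127 to 0.150 in DM-PBS and -0.149 to -0.0614 in DM-AA. The AA fold changes therefore fell with GC content in both media, with a rho of -0.274 in GM and -0.266 in DM across genes. With each library's GC and length trend removed, an alternative chosen after the trend had been seen, 1983 of the 2534 genes called in GM and 2574 of the 3230 called in DM were still past the test.

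**Figure D2:**
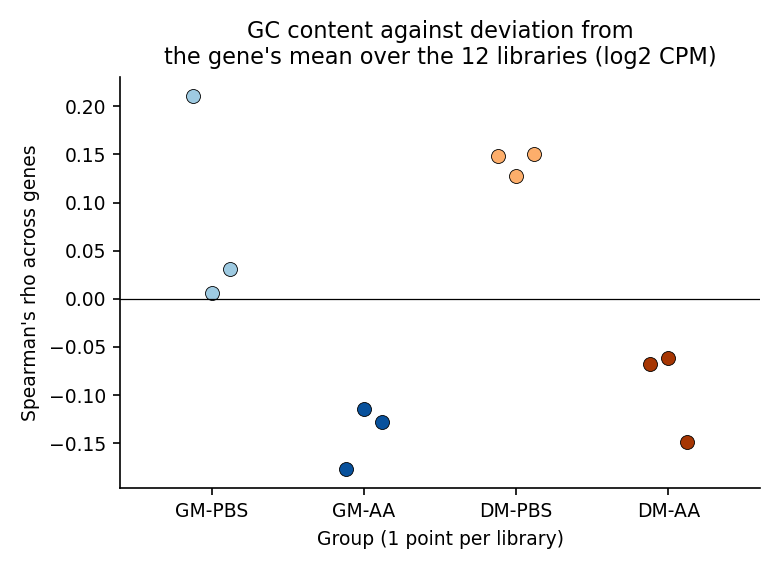
Spearman's rho across 12143 genes between transcript GC content and each library's deviation from the gene's mean over all 12 libraries (log2 CPM), 1 point per library in 4 groups. The 3 AA libraries of each medium lie below its 3 PBS libraries, with a gap of at least 0.120.

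Some abundant genes could not be measured. Gapdh, Ppia and Rpl10 were listed at 0 reads in all 12 libraries, and 17 of 81 ribosomal protein genes had a mean of 0 reads; such genes have many near-identical copies in the genome. The actin genes Acta1 and Actc1, the Sprr2 genes and the histone gene Hist1h2af also belong to families of near-identical sequences, and their values are uncertain for that reason. The strand of the reads was not used in what follows, so genes that overlap others are uncertain as well. Exons of genes on the opposite strand covered 35.3% of Hist1h2af, 23.4% of Ccnd1, 23.2% of Ctgf, 23.1% of Mest, 20.7% of Cebpb, 22.8% of Ube2c, 19.4% of Txnip, 18.3% of Fdft1, 15.5% of Ckm, 15.0% of Cebpd, 14.5% of Pim1, 12.6% of Oxct1 and 11.1% of Prc1, and exons of another gene on the same strand covered 18.8% of Spp1.

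In growth medium, the lists of ERK-responsive, inflammation and NF-kB, Notch and Id, and G1/S and DNA replication genes lay below other genes in cells given AA, and the sarcomere list lay above them; none of these lists passed with an estimated correlation. Egr1, an immediate early transcription factor, fell from 286 ± 15.1 to 159 ± 4.32 CPM (mean ± SD). Cxcl5, a neutrophil chemokine, fell from 311 ± 20.3 to 155 ± 14.2 CPM, and Myom2, a protein of the sarcomere's M-band, rose from 17.8 ± 1.37 to 38.5 ± 0.903 CPM. In all, 2534 of the 12230 genes were past the test, 1194 higher and 1340 lower. Most changes were small: 154 of the higher and 178 of the lower genes differed by at least 1.5-fold.

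The list of ERK-responsive and immediate early genes, whose transcription follows growth-factor signalling, had the lowest adjusted p. Of 26 members, 18 fell and 1 rose (19 and 1 adjusted over the list alone), and the list lay below other genes. The ERK-responsive list had adjusted p = 5.62e-10 (camera), and adjusted p = 0.0958 with an estimated correlation. Egr1 fell by 0.85 ± 0.053, Egr2 fell by 0.89 ± 0.084, the growth regulator Myc fell by 0.77 ± 0.061, and Dusp6, the phosphatase that ERK signalling induces against ERK itself, fell by 0.77 ± 0.068. Of 12 inflammation and NF-kB genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone). The inflammation list had adjusted p = 2.61e-05 (camera), and adjusted p = 0.106 with an estimated correlation. Among them Cxcl5 fell by 1.01 ± 0.070, the monocyte chemokine Ccl2 fell by 0.60 ± 0.072, and Ptgs2, the inducible cyclooxygenase, fell by 0.59 ± 0.052.

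Sarcomere genes were the only list higher with AA in GM among the 22 tested. Of 28 members, 11 rose and 0 fell (17 and 0 adjusted over the list alone). Many members had few reads: over all 37 members, tested or not, the median level was 3.23 CPM, with Des the highest at 1620 CPM. The sarcomere list had adjusted p = 5.07e-08 (camera), and adjusted p = 0.110 with an estimated correlation. Myom2 rose by 1.12 ± 0.095, titin (Ttn) by 0.99 ± 0.10, and the acetylcholine receptor subunits Chrnd and Chrna1 by 0.59 ± 0.058 and 0.36 ± 0.046. Among the myogenic regulators, Myf5, a determination factor of myoblasts, rose by 0.64 ± 0.072, while Myod1, the other determination factor, fell by 0.34 ± 0.049. Notch and Id genes were lower, with 6 of 13 down and 0 up (6 and 0 adjusted over the list alone). The Notch and Id list had adjusted p = 0.00422 (camera), and adjusted p = 0.308 with an estimated correlation. Id1 and Id2, inhibitors of the MyoD family of transcription factors, were at -0.52 ± 0.052 and -0.46 ± 0.063.

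Genes of DNA replication were modestly lower in GM. Of 31 G1/S and DNA replication genes, 10 fell and 0 rose (12 and 0 adjusted over the list alone). The G1/S list had adjusted p = 9.42e-04 (camera), and adjusted p = 0.0958 with an estimated correlation. It included the replicative helicase subunits Mcm5 and Mcm7 at -0.21 ± 0.049 and -0.25 ± 0.052 and the thymidine kinase Tk1 at -0.23 ± 0.056. Of 26 G2/M and mitosis genes, 4 fell and 0 rose (3 and 0 adjusted over the list alone). The G2/M list had adjusted p = 0.0239 (camera), and adjusted p = 0.455 with an estimated correlation. The mitotic kinase Aurkb was at -0.25 ± 0.054. This G2/M call was lost without GM-PBS 3, GM-AA 1 or GM-AA 2 (adjusted p = 0.0635, 0.0743 and 0.0535). Without GM-AA 1 only 1 member of the G2/M list fell past the test, and without GM-PBS 1, GM-PBS 3 or GM-AA 2 there were 2. With the GC and length trend removed the calls of the members Plk1 and Cdc20 were lost (adjusted p = 0.0781 and 0.0803). Sterol synthesis genes were lower, 8 of 21 falling and 2 rising (9 and 2 adjusted over the list alone). The sterol list had adjusted p = 0.0170 (camera), and adjusted p = 0.308 with an estimated correlation. Insig1, which holds the sterol-sensing complex in the endoplasmic reticulum, fell by 0.67 ± 0.075, whereas Sc4mol, a demethylation enzyme of the pathway, rose by 0.31 ± 0.055. Without GM-PBS 1 or GM-AA 3 the sterol genes that fell numbered 4. Glycolysis genes were lower, with 4 of 18 down and 0 up (4 and 0 adjusted over the list alone). The glycolysis list had adjusted p = 0.00882 (camera), and adjusted p = 0.308 with an estimated correlation. It included the glucose transporter Slc2a1 at -0.30 ± 0.053 and Pfkl at -0.28 ± 0.052. The glycolysis call was lost with the GC and length trend removed (adjusted p = 0.0530).

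No other list passed the camera test in GM (adjusted p from 0.0546 to 0.985). Counts past the test are followed in brackets by those rising and falling adjusted over the list alone. Over all comparisons, 47 counts of 4 or fewer moved by over 1.5 times without 1 library. Among extracellular matrix and TGF-beta genes 3 rose and 9 fell of 22 (5 and 10). Among IGF and atrophy genes 5 rose and 6 fell of 18 (5 and 7). Among myoblast fusion genes 3 rose and 5 fell of 18 (4 and 5); 3 fell without GM-PBS 1, GM-AA 1 or GM-AA 3. Among myogenic regulators 3 rose and 1 fell of 12 (3 and 1). Timp1, an inhibitor of matrix proteases, fell by 0.70 ± 0.046 and the collagen cross-linking enzyme Lox fell by 0.51 ± 0.049. Of 2 muscle ubiquitin ligases in that list, Fbxo32 fell by 0.72 ± 0.049, while Trim63, chosen after its values were seen and with few reads (0.23 CPM in GM-PBS and 1.08 in GM-AA), rose by 2.11 ± 0.55 in GM (adjusted p = 0.00516) and by 1.55 ± 0.43 in DM (adjusted p = 0.00641). Igfbp5, an IGF-binding protein, rose by 0.57 ± 0.046. Of the cell cycle exit genes 2 rose and 3 fell of 15 (2 and 3). Of ketone body genes 1 rose and 1 fell of 10 (3 and 3). Of fatty acid oxidation and PPAR genes 3 rose and 3 fell of 19 (3 and 3). Of TCA cycle and respiratory chain genes 5 rose and 0 fell of 28 (5 and 0). Of NRF2 and oxidative stress genes 1 rose and 3 fell of 19 (1 and 3). For ER stress and integrated stress response genes 6 rose and 3 fell of 20 (6 and 3); 3 rose without GM-PBS 1 and 2 without GM-AA 1. For p53 targets 5 rose and 0 fell of 14 (5 and 0); 3 rose without GM-PBS 1, GM-AA 1, GM-AA 2 or GM-AA 3. For interferon response genes 1 rose and 1 fell of 13 (1 and 1). For ribosome biogenesis genes 2 rose and 0 fell of 16 (2 and 0). For control genes 2 rose and 1 fell of 10 (2 and 2). The stress regulator Atf4 rose by 0.40 ± 0.049, the pro-apoptotic gene Pmaip1 rose by 0.70 ± 0.083, and Idh3a, a subunit of isocitrate dehydrogenase, rose by 0.35 ± 0.052. The p53 list passed without GM-PBS 1 or GM-AA 2 (adjusted p = 0.0154 and 0.00332). The matrix list passed without GM-PBS 1, GM-AA 2 or GM-AA 3 (adjusted p = 0.0217, 0.0279 and 0.0369). The TCA list passed without GM-PBS 1 or GM-AA 3 (adjusted p = 0.0187 and 0.0157). With the GC and length trend removed, the TCA list (adjusted p = 0.0124) and the p53 list (adjusted p = 0.0289) passed as well. The median, mean and camera direction differed in sign for the fatty acid oxidation and NRF2 lists.

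Among the markers of other cell types, with list medians from 0.0247 to 0.195 CPM, Spp1 (osteopontin, also made by C2C12 cells) fell by 1.02 ± 0.049 and the chondrocyte regulator Sox9 fell by 0.56 ± 0.058. All 3 tested genes of the osteoblast and chondrocyte list fell (3 adjusted over the list alone), as did 1 of 3 adipocyte genes (1 adjusted over the list alone, beside 1 higher) and Krt19, the 1 tested epithelial gene (1 adjusted over the list alone), at -0.27 ± 0.057. Of immune markers, 0 of 1 tested gene was past the test (0 adjusted over the list alone), and no endothelial marker had enough reads to be tested.

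The genes with the largest changes in GM, with the 3 AA libraries all on one side of the 3 PBS libraries, included further muscle proteins. Pdlim3 and Synpo2l, proteins of the Z-disc, rose by 1.31 ± 0.099 and 1.11 ± 0.086, the skeletal myosin light chain kinase Mylk2 by 1.01 ± 0.093 and the muscle carbonic anhydrase Car3 by 0.93 ± 0.15. Tpsab1, a tryptase of mast cells, rose by 1.20 ± 0.093 and the serpin Serpinb6b by 0.98 ± 0.14. The R-spondin receptor Lgr6 fell by 1.86 ± 0.11, the nuclear receptor Nr4a2 fell by 1.57 ± 0.10, the kinase gene Pim1 fell by 1.20 ± 0.11 and the inducible nitric oxide synthase Nos2 fell by 1.20 ± 0.10. The growth factor Fgf7 fell by 1.15 ± 0.074 and the protease inhibitor Slpi fell by 1.08 ± 0.18.

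Of the remaining genes chosen for every comparison, cyclin D1 (Ccnd1) fell by 0.15 ± 0.047 (adjusted p = 0.0176). Myog, the transcription factor of terminal differentiation, rose by 0.35 ± 0.13 (adjusted p = 0.0489) and the embryonic myosin Myh3 rose by 0.56 ± 0.15 (adjusted p = 0.00670). These calls were lost for Ccnd1 without GM-AA 2, GM-PBS 1 or GM-PBS 2, adjusted p = 0.0526 to 0.0942, for Myog without GM-AA 2, GM-AA 3, GM-PBS 1, GM-PBS 2 or GM-PBS 3, adjusted p = 0.0531 to 0.275, and for Myh3 without GM-AA 3, adjusted p = 0.0742. The proliferation marker Mki67 (-0.091 ± 0.056), the satellite cell factor Pax7 (0.10 ± 0.090), the cell cycle inhibitor Cdkn1a (-0.056 ± 0.047), the muscle creatine kinase Ckm (0.95 ± 0.40) and Oxct1, the mitochondrial enzyme that activates AA (0.12 ± 0.050), did not pass the test (adjusted p = 0.267, 0.454, 0.435, 0.0921 and 0.0756). Without GM-AA 1 the adjusted p of Ckm was 0.0327. Without GM-AA 3 that of Oxct1 was 0.0276, and that of Mki67 with the GC and length trend removed was 0.0401. Ckm, with 7 to 24 reads per GM library, also passed with no low-count filter (adjusted p = 0.0388), and the Myog call was lost when only the GM groups were fitted (adjusted p = 0.0587).

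In differentiation medium, the sarcomere, G1/S and G2/M lists were higher with AA, and the ERK-responsive, inflammation and sterol synthesis lists were lower. Myog rose from 70.2 ± 3.07 to 135 ± 11.5 CPM (mean ± SD) and the cardiac actin Actc1, which is expressed in developing muscle, from 15.8 ± 0.757 to 49.4 ± 8.62 CPM. Rrm2, a ribonucleotide reductase subunit needed for DNA synthesis, rose from 171 ± 4.19 to 238 ± 11 CPM, and Cxcl5 fell from 214 ± 25.7 to 59.8 ± 7.61 CPM. In all, 3230 genes were past the test, 1538 higher and 1692 lower, of which 225 and 289 differed by at least 1.5-fold.

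**Figure D3:**
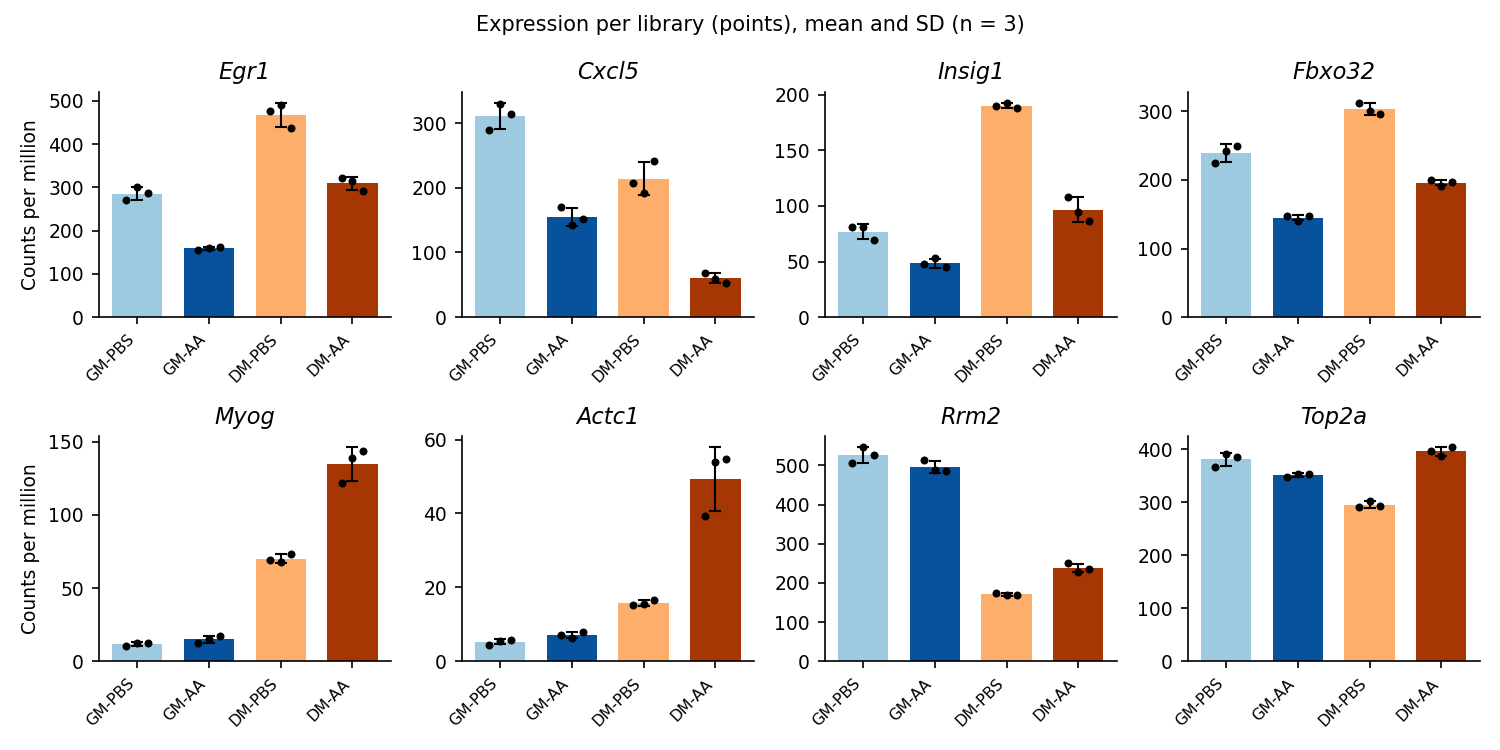
CPM in each library (points) with the group mean (bars, starting at 0) and SD (error bars, n = 3) for 8 genes in 4 groups. Egr1, Cxcl5, Insig1 and Fbxo32 were lower with AA in both media, and Rrm2 and Top2a were higher with AA in DM, where Myog rose from 70.2 to 135 CPM.

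Of 28 sarcomere and contractile genes, 23 rose and 0 fell (25 and 0 adjusted over the list alone), the largest list median in DM. The sarcomere list had adjusted p = 9.24e-15 (camera), and adjusted p = 0.0261 with an estimated correlation. Actc1 rose by 1.64 ± 0.11, the skeletal actin Acta1 by 1.51 ± 0.12, the calcium release channel Ryr1 by 1.17 ± 0.11 and the fast-fibre actinin Actn3 by 0.58 ± 0.056. Among myogenic regulators 5 rose and 2 fell of 12 (5 and 2) past the test, with counts adjusted over the list alone in brackets, and the list as a whole did not pass (camera, adjusted p = 0.101). Myog rose by 0.94 ± 0.066 and Mef2a by 0.48 ± 0.061. Tmem8c (myomaker), the membrane protein required for myoblast fusion, rose by 1.49 ± 0.13 and the muscle cadherin Cdh15 by 0.41 ± 0.047, while the fusion list, in which 8 rose and 6 fell of 18 (8 and 6), did not pass (adjusted p = 0.770); without DM-AA 3 its members that rose numbered 5.

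Cell cycle genes rose in the same libraries. Of 26 G2/M and mitosis genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone). The G2/M list had adjusted p = 7.31e-13 (camera), and adjusted p = 0.0261 with an estimated correlation. It included topoisomerase Top2a at 0.42 ± 0.044, Ube2c at 0.53 ± 0.057 and Prc1 at 0.35 ± 0.049. Of 31 G1/S and DNA replication genes, 18 rose and 2 fell (19 and 2 adjusted over the list alone). The G1/S list had adjusted p = 3.42e-09 (camera), and adjusted p = 0.0102 with an estimated correlation. The transcription factor E2f2 rose by 0.66 ± 0.058, Rrm2 by 0.48 ± 0.050 and cyclin D3 (Ccnd3), which is induced during myoblast differentiation, by 0.44 ± 0.053. Ccnd1 went the other way and fell by 0.34 ± 0.050. Ribosome biogenesis genes were higher, 7 of 16 rising and 0 falling (7 and 0 adjusted over the list alone). The ribosome biogenesis list had adjusted p = 8.67e-04 (camera), and adjusted p = 0.0261 with an estimated correlation. It included Nop58 at 0.39 ± 0.068. TCA cycle and respiratory chain genes were higher too, with 10 of 28 up and 0 down (11 and 0 adjusted over the list alone). The TCA list had adjusted p = 8.67e-04 (camera), and adjusted p = 0.238 with an estimated correlation. It included Idh3a at 0.43 ± 0.058 and Idh2 at 0.21 ± 0.049. The members that rose numbered 6 without DM-PBS 1 and 3 without DM-AA 3.

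ERK-responsive and immediate early genes were lower in DM as well. Of 26 members, 18 fell and 0 rose (19 and 1 adjusted over the list alone). The ERK-responsive list had adjusted p = 2.63e-10 (camera), and adjusted p = 0.0261 with an estimated correlation. Egr2 fell by 1.10 ± 0.079, Dusp6 fell by 0.90 ± 0.066, Egr1 fell by 0.60 ± 0.050 and Dusp4 fell by 0.58 ± 0.057. Of 12 inflammation and NF-kB genes, 9 fell and 0 rose (11 and 1 adjusted over the list alone). The inflammation list had adjusted p = 1.57e-07 (camera), and adjusted p = 0.0261 with an estimated correlation. It included Cxcl5 at -1.84 ± 0.080, Ccl2 at -0.90 ± 0.081, Cxcl1 at -0.93 ± 0.091 and Ptgs2 at -0.82 ± 0.072. Sterol synthesis genes were lower, 15 of 21 falling and 1 rising (18 and 1 adjusted over the list alone). The sterol list had adjusted p = 3.91e-08 (camera), and adjusted p = 0.0261 with an estimated correlation. Insig1 fell by 0.98 ± 0.063 and the lanosterol synthase Lss fell by 0.53 ± 0.062. Extracellular matrix and TGF-beta genes were lower, with 11 of 22 down and 4 up (11 and 4 adjusted over the list alone). The matrix list had adjusted p = 0.00270 (camera), and adjusted p = 0.248 with an estimated correlation. It included Ctgf at -0.90 ± 0.059, Lox at -0.76 ± 0.050 and the matrix protein Thbs1 at -0.59 ± 0.051. Of the osteoblast and chondrocyte markers, all 3 tested fell (3 adjusted over the list alone), with Spp1 at -1.39 ± 0.049 and Sox9 at -0.70 ± 0.062. Of 3 adipocyte markers 2 fell (3 adjusted over the list alone), with Cebpa, also active in other mesenchymal cells, at -0.85 ± 0.11; without any 1 of the DM libraries except DM-PBS 1, only 1 adipocyte marker fell. The 1 epithelial and the 1 immune marker tested did not pass the test (0 of 1 each adjusted over the list alone).

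**Figure D4:**
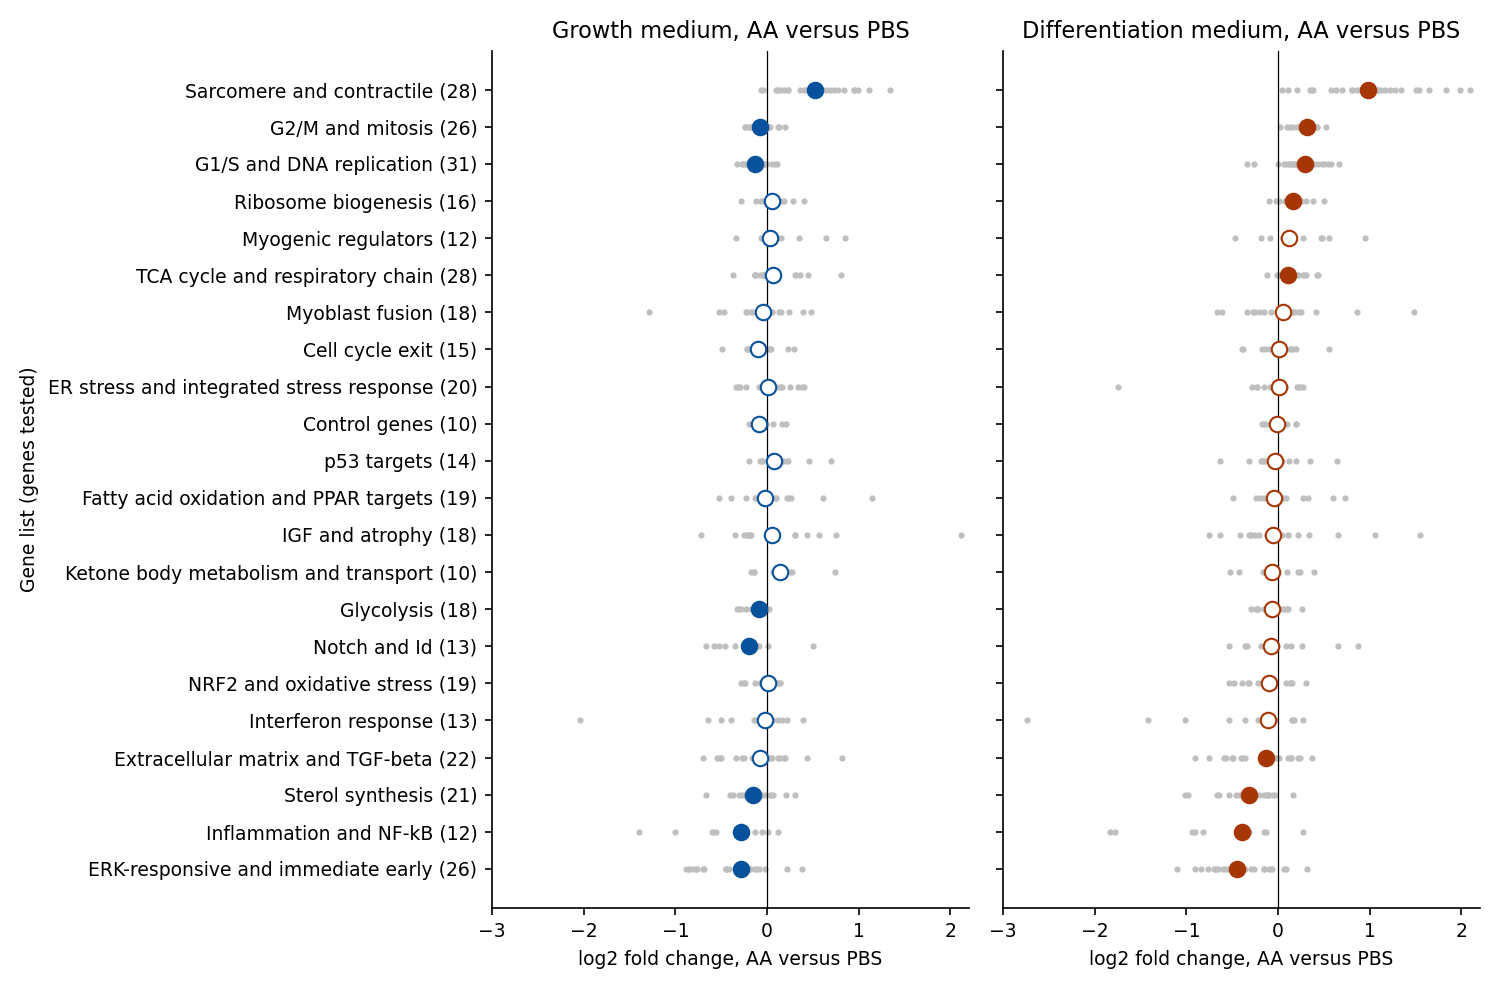
Median log2 fold change of AA against PBS in GM (left) and DM (right) for the 22 gene lists tested (large circles), over the values of their members (small grey points). Filled circles are lists past the camera test with a preset correlation, 8 in GM and 9 in DM, and open circles are the others; sarcomere genes lie highest and ERK-responsive genes lowest in DM.

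The other lists did not pass the camera test in DM (adjusted p from 0.101 to 0.924), with counts adjusted over the list alone again in brackets. Among IGF and atrophy genes 5 rose and 8 fell of 18 (7 and 8). Among Notch and Id genes 3 rose and 3 fell of 13 (3 and 3). Among cell cycle exit genes 2 rose and 3 fell of 15 (2 and 3). Among ketone body genes 1 rose and 3 fell of 10 (1 and 3). Fbxo32 fell by 0.63 ± 0.048, Igfbp4 fell by 0.76 ± 0.060 and Id1 fell by 0.54 ± 0.075. The cytosolic thiolase Acat2 and the AA-activating synthetase Aacs were at -0.52 ± 0.051 and -0.43 ± 0.054. The growth arrest gene Gadd45g rose by 0.55 ± 0.067. Of fatty acid oxidation and PPAR genes 1 rose and 1 fell of 19 (1 and 1). Of glycolysis genes 0 rose and 5 fell of 18 (0 and 5). Of NRF2 genes 2 rose and 6 fell of 19 (3 and 6). Of ER stress genes 3 rose and 2 fell of 20 (3 and 2). For p53 targets 2 rose and 4 fell of 14 (3 and 5). For interferon response genes 0 rose and 4 fell of 13 (0 and 4). For control genes 2 rose and 2 fell of 10 (2 and 2). The interferon-induced gene Ifit1 fell by 2.74 ± 0.33, from 36 to 42 reads per DM-PBS library to 3 to 7 per DM-AA library. The median, mean and camera direction differed in sign for the cell cycle exit, Notch and Id, IGF, fatty acid oxidation, ER stress and control lists.

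The largest changes in DM, with all 3 AA libraries on one side of the 3 PBS libraries, included more muscle genes. The fast myosin light chain Mylpf rose by 1.84 ± 0.21, the sarcomere assembly protein Klhl41 by 1.71 ± 0.13 and the muscle methyltransferase Smyd1 by 1.54 ± 0.12. Nkd2, an antagonist of Wnt signalling, rose by 1.72 ± 0.11 and Enpp2, the secreted enzyme autotaxin, by 1.70 ± 0.13. Fgf7 fell by 1.85 ± 0.086, the transcription factors Cebpb and Cebpd were at -1.75 ± 0.34 and -1.52 ± 0.095, the retinal reductase Dhrs3 fell by 1.48 ± 0.10 and Gprin3 fell by 1.40 ± 0.099. Cebpb had an SD of 67.7% of its mean reads within DM-PBS, and its call was lost with edgeR's robust option (adjusted p = 0.0869).

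Of the other genes chosen for every comparison, Myh3 rose by 1.53 ± 0.17, Cdkn1a by 0.20 ± 0.047, Mki67 by 0.22 ± 0.056 (adjusted p = 0.00369) and Ckm by 1.09 ± 0.38 (adjusted p = 0.0298). The calls were lost for Mki67 without DM-PBS 3, adjusted p = 0.0556, and for Ckm without DM-AA 2 or DM-PBS 2, adjusted p = 0.162 to 0.370. With DESeq2 the adjusted p of Ckm was 0.0664. Myod1 (0.059 ± 0.050), Pax7 (0.054 ± 0.076) and Oxct1 (-0.087 ± 0.051) did not pass the test (adjusted p = 0.425, 0.649 and 0.222). With the GC and length trend removed, the adjusted p of Myod1 was 0.0162.

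The AA responses of the 2 media were compared gene by gene; they share no library. The same 553 genes were higher with AA in both media, against 150.2 if the lists were independent (Fisher's exact test, one-sided, odds ratio 8.80). Another 788 were lower in both, against 185.4 (odds ratio 15.8). A further 55 moved in opposite directions, 23 of them higher in GM and lower in DM. Fold changes correlated across the 12230 genes with Spearman's rho of 0.493. With the GC and length trend removed, 1229 genes were called in the same direction in both media, 556 higher and 673 lower, against 146.1 and 155.6 for independent lists, and rho was 0.446. Genes that passed the test in the same direction in both media include Egr1, Egr2, Dusp6, Cxcl5, Ccl2, Ptgs2, Insig1, Fbxo32, Id1, Lox, Spp1, Sox9 and Fgf7, all lower, and Cdh15, Atf4, Pmaip1 and Idh3a, all higher. Values not given above were, in GM, 0.39 ± 0.051 for Cdh15, and in DM 0.28 ± 0.049 for Atf4 and 0.64 ± 0.080 for Pmaip1.

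The size of the AA effect was then tested between the media (effect in DM minus effect in GM). The cell cycle lists had a higher AA effect in DM than in GM. Top2a differed by 0.54 ± 0.062, Rrm2 by 0.57 ± 0.067 and Aurkb by 0.54 ± 0.079. Acta1, at 1.02 ± 0.16, rose more with AA in DM, the muscle kinase Mylk2, at -1.20 ± 0.16, went the other way, and Cxcl5, at -0.83 ± 0.11, fell more in DM. In all, 641 genes were past the test, 315 with a more positive effect in DM and 326 with a more negative one, of which 54 and 62 differed by at least 1.5-fold.

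Of 26 G2/M and mitosis genes, 20 had a more positive AA effect in DM and 0 a more negative one (23 and 0 adjusted over the list alone). The G2/M list had adjusted p = 1.50e-22 (camera), and adjusted p = 0.0146 with an estimated correlation. Its median difference was 0.35. Of 31 G1/S and DNA replication genes, 18 were more positive and 0 more negative (26 and 1 adjusted over the list alone). The G1/S list had adjusted p = 4.03e-20 (camera), and adjusted p = 5.32e-04 with an estimated correlation. Its median difference was 0.40. Mcm5 and Mcm2, subunits of the replicative helicase, differed by 0.58 ± 0.076 and 0.51 ± 0.075, and the mitotic kinase Cdk1 by 0.50 ± 0.081. Of the cell cycle exit genes, in which 2 were more positive and 1 more negative of 15 (3 and 3 adjusted over the list alone; camera, adjusted p = 0.232), Gadd45g differed by 0.74 ± 0.092. Sarcomere genes had 5 more positive and 0 more negative of 28 (9 and 1 adjusted over the list alone). The sarcomere list had adjusted p = 5.39e-05 (camera), and adjusted p = 0.222 with an estimated correlation. It included Actc1 at 1.22 ± 0.22 and Myh3 at 0.97 ± 0.24, and the members past the test numbered 3 without GM-PBS 2, GM-PBS 3, GM-AA 1 or DM-PBS 1. Notch and Id genes had 1 more positive of 13, Id2 at 0.71 ± 0.12, and 0 more negative (2 and 0 adjusted over the list alone). The Notch and Id list had adjusted p = 0.00614 (camera), and adjusted p = 0.241 with an estimated correlation. Ribosome biogenesis genes passed as a list, though 0 members were more positive and 0 more negative of 16 past the test by edgeR (0 and 0 adjusted over the list alone, and 3 at an unadjusted p under 0.05). The ribosome biogenesis list had adjusted p = 0.0224 (camera), and adjusted p = 0.158 with an estimated correlation. That call was lost without GM-PBS 1 or GM-AA 3 (adjusted p = 0.0557 and 0.0743).

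Sterol synthesis genes had a more negative AA effect in DM, with 5 of 21 members more negative and 0 more positive (7 and 0 adjusted over the list alone). The sterol list had adjusted p = 5.39e-05 (camera), and adjusted p = 0.101 with an estimated correlation. So had inflammation and NF-kB genes, with 3 of 12 more negative and 0 more positive (7 and 0 adjusted over the list alone). The inflammation list had adjusted p = 0.0134 (camera), and adjusted p = 0.241 with an estimated correlation. Sc4mol was at -0.46 ± 0.076, Lss at -0.44 ± 0.099, Cxcl5 at -0.83 ± 0.11 and the adhesion molecule Vcam1 at -0.33 ± 0.072. Of 10 ketone body metabolism and transport genes, 2 were more negative and 0 more positive (4 and 0 adjusted over the list alone). The ketone body list had adjusted p = 0.0134 (camera), and adjusted p = 0.101 with an estimated correlation. The 2 members were Acat2 at -0.38 ± 0.076 and Aacs at -0.28, and the Aacs call was lost without each of 7 libraries. Oxct1, the mitochondrial enzyme that activates AA, did not pass the test. The p53 targets had 1 of 14 more negative and 1 more positive (4 and 1 adjusted over the list alone). The p53 list had adjusted p = 0.0134 (camera), and adjusted p = 0.241 with an estimated correlation. It included the p53-responsive kinase Plk2 at -0.49 ± 0.072. Without 1 library the more negative members ranged from 2 to 6 for sterol (2 or 3 without GM-PBS 2 or 3, GM-AA 1 or 2, DM-PBS 1 or 2, or DM-AA 2 or 3), from 2 to 6 for inflammation (6 without DM-AA 1) and from 1 to 2 for ketone genes (1 without GM-PBS 2 or 3, DM-PBS 1 or 3, or DM-AA 1 or 3). The inflammation call was lost without GM-PBS 1 (adjusted p = 0.0531) and the p53 call without GM-PBS 2, GM-AA 3 or DM-AA 1 (adjusted p = 0.0766, 0.0565 and 0.0563).

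Counts past the interaction test are given next as members with a more positive and a more negative effect in DM, with counts adjusted over the list alone in brackets, for lists that did not pass (camera, adjusted p from 0.104 to 0.857). They were 1 and 7 of 22 matrix genes (1 and 8), among them Thbs1 at -0.55 ± 0.073, the periostin gene Postn at -0.68 ± 0.13 and decorin (Dcn) at -0.83 ± 0.19. They were 1 and 2 of 18 IGF genes (1 and 3), with Igfbp5 at -0.35 ± 0.065 and Igfbp4 at -0.51 ± 0.099. They were 3 and 1 of 12 myogenic regulators (4 and 2). For ERK-responsive genes they were 1 and 1 of 26 (2 and 2), with Dusp4 at -0.49 ± 0.077, and 1 and 0 of 18 fusion genes (1 and 0). For the metabolic lists they were 1 and 0 of 19 fatty acid oxidation genes (1 and 0), with the secreted lipase inhibitor Angptl4 at 0.58 ± 0.096. They were 0 and 0 of 28 TCA genes (0 and 0) and 0 and 0 of 18 glycolysis genes (0 and 0). For NRF2 genes they were 0 and 2 of 19 (0 and 3), with the glutathione synthesis gene Gclm at -0.63 ± 0.13. For ER stress genes they were 0 and 0 of 20 (0 and 2), for interferon response genes 0 and 0 of 13 (0 and 0) and for control genes 0 and 0 of 10 (0 and 0). Without GM-AA 1 the IGF, TCA and matrix lists passed (adjusted p = 0.0206, 0.0194 and 0.0229), as did the TCA list without DM-AA 2 (0.0371). Of other cell types, Spp1 was at -0.37 ± 0.069, with 1 of 3 osteoblast and chondrocyte genes and 1 of 3 adipocyte genes more negative (1 and 1 adjusted over the lists alone). The 1 epithelial and the 1 immune gene did not pass (1 and 0 more positive adjusted over the lists alone). The median and mean of the ER stress list were below 0 while its camera direction was up.

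Among single genes with the largest differences, the profilin gene Pfn2 was at 1.06 ± 0.17, Mylpf at 1.20 ± 0.34 and Hist1h2af at 1.31 ± 0.37. The acute-phase gene Saa3 was at -1.58 ± 0.37, Tpsab1 at -1.27 ± 0.32, Mylk2 at -1.20 ± 0.16 and the tissue factor gene F3 at -1.19 ± 0.14. The calls were lost for Mylpf without DM-AA 2, DM-AA 3, DM-PBS 1, DM-PBS 2, GM-AA 1, GM-AA 2, GM-PBS 2 or GM-PBS 3, adjusted p = 0.0509 to 0.119, for Hist1h2af without DM-AA 1, DM-AA 2, DM-PBS 1, DM-PBS 2, GM-AA 2, GM-AA 3, GM-PBS 1 or GM-PBS 3, adjusted p = 0.0525 to 0.168, and for Tpsab1 without DM-PBS 1 or DM-PBS 3, adjusted p = 0.0522 to 0.144. With edgeR's robust option the calls of Mylpf and Hist1h2af were lost as well (adjusted p = 0.0552 and 0.426), and with DESeq2 that of Hist1h2af (adjusted p = 0.464). Tpsab1 had 8 to 21 reads per DM library and Saa3 13 to 51. Of the genes chosen for every comparison, Myod1 (0.40 ± 0.070), Myog (0.59 ± 0.15), Mki67 (0.31 ± 0.079) and Cdkn1a (0.25 ± 0.066) had more positive effects in DM. These calls were lost for Myog without GM-AA 1 or GM-PBS 3, adjusted p = 0.0510 to 0.0602, for Mki67 without DM-PBS 3, adjusted p = 0.0558, and for Cdkn1a without DM-AA 3 or GM-AA 2, adjusted p = 0.0515 to 0.0832. Tmem8c was at 1.01 ± 0.23, with its call lost without GM-PBS 2, adjusted p = 0.0518. The differences for Ccnd1 (-0.18 ± 0.068), Pax7 (-0.049 ± 0.12), Ckm (0.14 ± 0.57) and Oxct1 (-0.21 ± 0.071) did not pass the test (adjusted p = 0.127, 0.896, 0.948 and 0.0823), and that of Oxct1 passed without GM-AA 3 (adjusted p = 0.0360).

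The media were compared in PBS-treated cells to set the AA responses beside the difference between the media. That difference includes any effect of the medium itself, which the design does not part from differentiation. In DM, Myog and the Notch target gene Heyl were higher, Id1, Id3 and the list of DNA replication genes were lower, and every tested sterol synthesis gene was higher. Myog rose from 11.8 ± 1.34 CPM in GM to 70.2 ± 3.07 in DM (mean ± SD) and Id1 fell from 241 ± 19.5 to 51.4 ± 1.30 CPM. In all, 6654 genes were past the test, 3299 higher and 3355 lower in DM, of which 1100 and 1055 differed by at least 1.5-fold.

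Of 31 G1/S and DNA replication genes, 29 fell and 1 rose in DM (29 and 1 adjusted over the list alone). The G1/S list had adjusted p = 1.42e-16 (camera), and adjusted p = 0.00103 with an estimated correlation. It included Rrm2 at -1.62 ± 0.049 and Mcm3 at -1.35 ± 0.049. G2/M and mitosis genes did not move as a list (adjusted p = 0.598; 11 rose and 8 fell of 26, 11 and 9 adjusted over the list alone); Ccnb2 rose by 1.01 ± 0.075 and Aurkb fell by 0.53 ± 0.056. All 21 sterol synthesis genes rose (21 and 0 adjusted over the list alone). The sterol list had adjusted p = 4.14e-11 (camera), and adjusted p = 0.0154 with an estimated correlation. It included Fdft1 at 1.22 ± 0.052 and Insig1 at 1.30 ± 0.064. Of 18 glycolysis genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone). The glycolysis list had adjusted p = 5.94e-07 (camera), and adjusted p = 0.0651 with an estimated correlation. It included the hexokinase Hk2 at -1.94 ± 0.053 and Slc2a1 at -1.46 ± 0.055. Ribosome biogenesis genes were lower, 12 of 16 falling and 0 rising (12 and 0 adjusted over the list alone). The ribosome biogenesis list had adjusted p = 5.98e-05 (camera), and adjusted p = 0.0205 with an estimated correlation. It included Nop56 at -0.89 ± 0.069. ER stress and integrated stress response genes were lower, 14 of 20 falling and 2 rising (14 and 2 adjusted over the list alone). The ER stress list had adjusted p = 0.00101 (camera), and adjusted p = 0.0651 with an estimated correlation. It included the asparagine synthetase Asns at -1.50 ± 0.086.

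Myogenic regulators were higher in DM, 8 of 12 rising and 3 falling (8 and 3 adjusted over the list alone). The myogenic list had adjusted p = 0.0200 (camera), and adjusted p = 0.259 with an estimated correlation. It included Myog at 2.58 ± 0.097. Sarcomere genes had 13 higher and 3 lower of 28 (13 and 3 adjusted over the list alone). The sarcomere list had adjusted p = 0.0325 (camera), and adjusted p = 0.421 with an estimated correlation. Ryr1 rose by 1.66 ± 0.16 and Ttn by 1.61 ± 0.099, whereas Acta1 fell by 1.34 ± 0.12. IGF and atrophy genes were higher, 10 of 18 rising and 2 falling (10 and 2 adjusted over the list alone). The IGF list had adjusted p = 0.0270 (camera), and adjusted p = 0.239 with an estimated correlation. It included Igfbp5 at 1.55 ± 0.047. Inflammation and NF-kB genes were lower, 8 of 12 falling and 1 rising (8 and 2 adjusted over the list alone). The inflammation list had adjusted p = 0.0358 (camera), and adjusted p = 0.301 with an estimated correlation. It included Ptgs2 at -1.48 ± 0.057. This call was lost without GM-PBS 2, DM-PBS 1 or DM-PBS 2 (adjusted p = 0.0599, 0.0532 and 0.0549) and with the GC and length trend removed (adjusted p = 0.0620). Notch and Id genes went both ways, 7 up and 3 down of 13 (7 and 3 adjusted over the list alone; camera, adjusted p = 0.270): Heyl rose by 5.69 ± 0.17, from 4 to 8 reads per GM-PBS library to 309 to 374 per DM-PBS library, and Id1 and Id3 were at -2.23 ± 0.060 and -2.29 ± 0.072.

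The other lists did not pass between the media (adjusted p from 0.0520 to 0.922), with counts adjusted over the list alone in brackets. Among extracellular matrix genes 13 rose and 7 fell of 22 (13 and 7), with Timp1 at -1.59 ± 0.048 and the collagen Col3a1 at 1.21 ± 0.049. Among ERK-responsive genes 7 rose and 11 fell of 26 (8 and 12), with Ier3 at -1.59 ± 0.060 and Egr1 at 0.71 ± 0.050. Among fusion genes 8 rose and 5 fell of 18 (9 and 5), with Cdh15 at 0.84 ± 0.050. Of cell cycle exit genes 9 rose and 4 fell of 15 (9 and 4). Of ketone body genes 3 rose and 3 fell of 10 (3 and 3), with the monocarboxylate transporter Slc16a3 at -1.20 ± 0.050. Of fatty acid oxidation genes 8 rose and 5 fell of 19 (8 and 5). Of TCA genes 7 rose and 4 fell of 28 (7 and 4). Of NRF2 genes 3 rose and 10 fell of 19 (3 and 10). For p53 targets 5 rose and 5 fell of 14 (5 and 5). For interferon response genes 7 rose and 1 fell of 13 (7 and 1). For control genes 1 rose and 6 fell of 10 (1 and 6); the control list passed without GM-PBS 3 or DM-PBS 3 (adjusted p = 0.0469 and 0.0394). Of other cell types, Krt19 fell by 1.58 ± 0.066 and Cd68, the 1 immune marker tested, fell by 0.93 ± 0.25 (1 and 1 lower adjusted over the lists alone). Further, 2 adipocyte genes rose and 1 fell of 3 (2 and 1 adjusted over the list alone), and 2 of 3 osteoblast and chondrocyte genes fell (2 adjusted over the list alone), with Spp1 at -0.17 ± 0.048. The median, mean and camera direction differed in sign for the G2/M, ketone body, TCA and p53 lists.

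Among the genes with the largest changes between the media, some that fell encode proteins of the cornified envelope, a structure of skin, which no list covered. Sprr2h had 106 to 122 reads per GM-PBS library and 0 in each DM-PBS library, at least 116-fold lower in DM against a floor of 3 counts over the group. Sprr2e, with 217 reads over the 3 GM-PBS libraries and 1 over the 3 DM-PBS libraries, was 222 times as high in GM (95% interval from counting alone, exact binomial, 39.5 to 8828). Lce1g, with 357 and 5 reads, was 73.2 times as high (31.1 to 226.8). These intervals and the floor cover counting error only. Sprr1a fell by 4.00 ± 0.12, the immune receptor gene Havcr2 fell by 3.40 ± 0.14 and Tpsab1 fell by 3.32 ± 0.17. The imprinted gene Mest rose by 3.62 ± 0.17, the matrix protein Ogn by 3.36 ± 0.080, the glucose-responsive gene Txnip by 3.34 ± 0.093, C1qtnf3 by 3.14 ± 0.10 and the Wnt-pathway formin Daam2 by 2.98 ± 0.079. Of the other genes chosen for every comparison, Pax7 rose by 0.75 ± 0.083. By contrast, Ccnd1 fell by 0.84 ± 0.048, Myod1 fell by 0.45 ± 0.049, Cdkn1a fell by 0.27 ± 0.047 and Myh3 fell by 0.99 ± 0.19. Oxct1 fell by 0.17 ± 0.050 (adjusted p = 0.00548), a call lost without DM-PBS 1, adjusted p = 0.0537. Mki67 (-0.11 ± 0.056) and Ckm (0.16 ± 0.46) did not pass the test (adjusted p = 0.0962 and 0.791); Mki67 passed without DM-PBS 1 or DM-PBS 2 (adjusted p = 0.0348 to 0.0434) and with the GC and length trend removed (adjusted p = 0.00304) or no low-count filter (adjusted p = 0.0310).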

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

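The tests of GC content, library scaling and leaving out single libraries were chosen after the results were seen, the bounds of the GC test being written before its own outcome, whereas the splits of the samples were chosen before.

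The results below stand here because the effect of AA differed between the 2 media by the test of the difference itself. It differed for 641 genes. For whole lists the median difference (DM minus GM, log2) was 0.40 for G1/S and DNA replication, 0.35 for G2/M and mitosis, 0.31 for sarcomere genes, 0.16 for Notch and Id, 0.12 for ribosome biogenesis, -0.19 for ketone body metabolism and transport, -0.18 for sterol synthesis, -0.11 for p53 targets and -0.28 for inflammation and NF-kB. With an estimated correlation only G1/S (adjusted p = 5.32e-04) and G2/M (adjusted p = 0.0146) passed, and the other 7 lists did not (adjusted p from 0.101 to 0.241). Among the genes named in the text it differed, with a more positive effect in DM, for Acta1 1.02, Actc1 1.22, Angptl4 0.58, Aurkb 0.54, Ccnd3 0.38, Cdk1 0.50, Cdkn1a 0.25, E2f2 0.57, Egr1 0.25, Gadd45g 0.74, Hist1h2af 1.31, Id2 0.71, Mcm2 0.51, Mcm3 0.37, Mcm5 0.58, Mef2a 0.33, Mki67 0.31, Myh3 0.97, Mylpf 1.20, Myod1 0.40, Myog 0.59, Nos2 0.97, Pfn2 1.06, Plk1 0.33, Prc1 0.42, Rrm2 0.57, Tk1 0.29, Tmem8c 1.01, Top2a 0.54 and Ube2c 0.50, and with a more negative effect in DM for Aacs -0.28, Acat2 -0.38, Asah1 -0.31, Atp6v1a -0.35, C1qtnf3 -0.62, Cebpd -0.87, Col3a1 -0.29, Ctgf -0.38, Cxcl5 -0.83, Dcn -0.83, Dusp4 -0.49, F3 -1.19, Fgf7 -0.70, Gclm -0.63, Gprin3 -0.79, Igfbp4 -0.51, Igfbp5 -0.35, Lox -0.25, Lss -0.44, Myf5 -0.37, Mylk2 -1.20, Neu1 -0.43, Ogn -0.94, Plk2 -0.49, Postn -0.68, Saa3 -1.58, Sc4mol -0.46, Spp1 -0.37, Thbs1 -0.55, Tpp1 -0.24, Tpsab1 -1.27, Txnip -1.005 and Vcam1 -0.33. Leaving out 1 library was checked only for genes that the naming rules gave for this difference. Of these, the call was lost, with the libraries and the adjusted p without each in brackets, for Aacs (DM-AA 1, DM-AA 3, DM-PBS 1, DM-PBS 3, GM-AA 3, GM-PBS 2, GM-PBS 3; 0.0523 to 0.115), Cdkn1a (DM-AA 3, GM-AA 2; 0.0515 to 0.0832), Egr1 (DM-AA 1, DM-AA 2, DM-PBS 1, DM-PBS 3, GM-AA 1, GM-AA 2, GM-PBS 2, GM-PBS 3; 0.0524 to 0.114), Hist1h2af (DM-AA 1, DM-AA 2, DM-PBS 1, DM-PBS 2, GM-AA 2, GM-AA 3, GM-PBS 1, GM-PBS 3; 0.0525 to 0.168), Mef2a (DM-AA 2, DM-AA 3, DM-PBS 3, GM-AA 1, GM-AA 2, GM-PBS 2, GM-PBS 3; 0.0633 to 0.10), Mki67 (DM-PBS 3; 0.0558), Myf5 (DM-AA 1, GM-AA 3, GM-PBS 1; 0.0618 to 0.0966), Mylpf (DM-AA 2, DM-AA 3, DM-PBS 1, DM-PBS 2, GM-AA 1, GM-AA 2, GM-PBS 2, GM-PBS 3; 0.0509 to 0.119), Myog (GM-AA 1, GM-PBS 3; 0.0510 to 0.0602), Tmem8c (GM-PBS 2; 0.0518) and Tpsab1 (DM-PBS 1, DM-PBS 3; 0.0522 to 0.144). Genes named here for other reasons, among them Asah1, Atp6v1a, Neu1 and Tpp1, were not checked in this way.

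Other splits of the libraries were counted for each comparison. For AA against PBS in GM, AA against PBS in DM and the media in PBS, 3 libraries against 3 make 10 splits, which cannot give a share under 0.05; the real split (1 of the 10, with 2534, 3230 and 6654 genes) was the only one as large in each, and the highest of the others called 0, 1 and 0 genes. For the difference of effects, 8 of the 100 splits drawn from 200 gave as many genes as the real one (641), and the highest other gave 4279, so chance cannot be excluded by this count. That highest split swaps AA and PBS within 1 medium, which turns the difference of the effects into their sum. A split that calls so many genes points to a structure of the samples, here the AA response shared by both media; of the 7 other splits as large, 6 kept the labels of 1 medium intact, and splits that mixed both media called 0 genes at most.

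Cell cycle lists moved apart between the media: with AA, the G1/S and G2/M lists lay higher in DM and lower in GM. In DM 18 of 31 G1/S genes rose and 2 fell, and 21 of 26 G2/M genes rose and 0 fell. In GM 10 G1/S and 4 G2/M genes fell and 0 rose, and most members did not pass the test. The G2/M call in GM was lost without each of 3 libraries, GM-PBS 3, GM-AA 1 and GM-AA 2 (camera, adjusted p = 0.0635, 0.0743 and 0.0535). With an estimated correlation neither list passed in GM (camera, adjusted p = 0.0958 for G1/S and 0.455 for G2/M). The smaller of the 2 median differences was 0.356 after removing the trend with GC content and gene length. Across genes, the difference of effects had a rho of only -0.00597 with GC content and -0.0487 with length. Removing the trend could therefore hardly move these medians. A bias that follows GC content or length across genes would show as such a trend in the difference of effects. Its near absence argues against such a bias as the cause for these 2 lists. The smallest median over 3 scalings of the libraries was 0.354. TMM factors ran only from 0.981 to 1.015, and counts only from 63.2% to 64.9% of the RPKM divisor. Scalings so alike could hardly change such a median. A scaling factor moves all genes of a library alike, however, and the median difference over all 12230 tested genes was -0.00113. That value argues against library scaling as the cause for these 2 lists. A single library as the cause is argued against by the smallest median without any of the 12 libraries, 0.333. A difference between dishes, in cell density or in the day of culture was not tested, since the labels give none of these. A response to AA that depends on the medium stays open, and no biological explanation was tested.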

How the results depend on the processing

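No list past the test, and no such gene of the naming rules, changed direction under the alternatives run, whereas lists and genes not past it did (with the GC and length trend removed, the fatty acid oxidation and NRF2 lists in GM and the Notch and Id and control lists in DM, and others without 1 library). The direction of the other called genes was not checked. Over single results of the genes of those rules, 5705 gene values stayed on the same side of the threshold, 271 fell below it and 10 rose above it, and 1047 list values stayed, 37 fell below and 16 rose above. Adding a threshold of 1.5-fold left 332 genes in GM, 514 in DM, 2155 between the media and 116 for the difference of effects, by construction of the setting. With an estimated correlation, 0 lists passed in GM (camera; 4 at an unadjusted p under 0.05, 13 past 5% FDR by fry, 8 with the preset correlation), 7 in DM, 3 between the media and 2 for the difference, of 9 each; the cause was not tested. Counting unadjusted p under 0.05, 2142 genes were shared between the AA responses in the same direction (1341 with adjusted p), by construction. Without 1 library, calls ranged from 1838 to 2234 in GM, 2384 to 2943 in DM, 6030 to 6182 between the media and 456 to 645 for the difference, the overlap from 1041 to 1260, and the lists past the test from 7 to 11, 9 to 9, 8 to 10 and 7 to 12. DESeq2's Wald test gave 1804, 2444, 5743 and 472 genes and an overlap of 976. Other counts moved by less than 1.5 times: 2288 to 2621 in GM, 3074 to 3352 in DM, 6095 to 6813 between the media and 590 to 823 for the difference. Which direction held more genes depended on the scaling. With the RPKM divisor, 1317 genes were higher and 1238 lower in GM (1194 and 1340 in the main fit). In DM they were 1690 and 1554 (1538 and 1692), and between the media 3574 and 3067 (3299 and 3355). With the replicate block, counts were 2444, 3109, 6588 and 590, the overlap 1272 and the lists 8, 9, 9 and 9; the 18 pairs of libraries with the same number had correlations of their deviations from -0.0676 to 0.0823, 0 of them over 0.1, so the numbers were not taken as pairs. Of 146 counts of list members above 0, 55 moved by over 1.5 times without 1 library, 47 of them counts of 4 or fewer. On data simulated at this depth, spread and number of libraries, 58.2% of the smallest changes tried were recovered; depth was not varied.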

Other observations

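The camera values of the ERK-responsive list in this part come from a list and tests written before the data were examined. All other tests in this part were chosen after the results were seen. The bounds of the GC test on the ERK-responsive list were written before that test's own outcome. The genes of this part that the report does not name were chosen after their values were seen.

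Lysosomal genes rose with AA in GM. Of 32 tested members of a list of lysosomal enzymes, membrane proteins and proton pump subunits, 20 rose and 0 fell (24 and 1 adjusted over the list alone; camera, adjusted p = 1.37e-09; adjusted p = 0.0134 with an estimated correlation). The sialidase Neu1 rose by 0.72 ± 0.057, the proton pump subunit Atp6v1a by 0.42 ± 0.044, the peptidase Tpp1 by 0.39 ± 0.047 and the ceramidase Asah1 by 0.32 ± 0.050 (n = 3 libraries per group). In DM 4 rose and 3 fell, and the list did not pass (adjusted p = 0.394); in PBS the list was itself lower in DM than in GM, with 29 members lower and 0 higher (29 and 1 adjusted over the list alone; median -0.497, adjusted p = 1.16e-10; adjusted p = 0.0134 with an estimated correlation). The effect was more negative in DM (camera on the difference, adjusted p = 1.62e-08; adjusted p = 0.0137 with an estimated correlation). AA may thus raise lysosomal genes more in GM than in DM, where they start from a lower level, a hypothesis found and tested on the same libraries, after the single values of lysosomal genes and of Wnt, imprinted, osmotic stress, YAP target and insulin-like growth factor genes had been looked at, for which the adjusted p does not account; 1 member, Gusb, is also in the control list.

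The ERK-responsive list was lower with AA in both media (with an estimated correlation, adjusted p = 0.0958 in GM and 0.0261 in DM). With the GC and length trend removed, the median nearer to 0 of the 2 media was -0.23, which argues against the fitted trend as the whole cause. The time between taking the dish and lysis could change transcripts induced within minutes; the median of 15 genes taken as slower ERK output was -0.25 in GM and -0.42 in DM, but their induction times were assumed and not measured, so handling time stays open. A response of these genes to AA stays open too, and no biological explanation was tested.

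The AA responses shared between the media went with a trend in GC content. After removing it, 1229 genes were still called in the same direction in both media, against 301.7 for independent lists. The fitted trend with GC content and length made up only 0.172% to 3.49% of the variance of a library's deviations. The fitted trend was thus not the whole of the shared response, but its removal does not decide on other effects of library preparation. In each medium the AA and PBS libraries did not overlap in their correlation with GC content, with a smaller gap of 0.120. A library preparation that differed with the treatment cannot be told apart from an effect of AA on GC-rich transcripts, since each AA library lies on one side of its PBS libraries.

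Axin2, Nkd2 and Tcf7, genes induced by Wnt signalling, were higher with AA in both media. They rose by 1.33 ± 0.18, 1.64 ± 0.15 and 0.59 ± 0.079 in GM, and by 1.58 ± 0.15, 1.72 ± 0.11 and 0.55 ± 0.076 in DM. The hypothesis that Wnt feedback genes rise as a set did not hold: of 13 tested members 3 rose and 4 fell in GM (camera, adjusted p = 0.762) and 6 rose and 4 fell in DM (adjusted p = 0.394), with medians of -0.03 and 0.25. Besides Axin2, Nkd2 and Tcf7, the members that rose in DM were Lgr5 by 2.23 ± 0.28, Lef1 by 0.43 ± 0.10 and Znrf3 by 0.40 ± 0.095. Lgr5, Lef1 and Znrf3 did not pass the test in GM. Those that fell, in both media, were Ccnd1, Dkk2, Lgr6 and Myc. Of these, Myc is also in the ERK-responsive list and Ccnd1 in the G1/S list. That result concerns the list as a whole and excludes neither a Wnt response of some members nor a counter-ion effect. The GC-trend tests above took the place of 2 further tests after that result was seen, of GC content on the Wnt list and of a lithium counter-ion, which the members, going both ways, would not have decided.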
